A study of Homo sapiens with 9 samples.

How the data were processed

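The data are polyA RNA-seq of 9 libraries, 3 each of HSPC, BFUE and CFUE cells. Per the labels' protocols, RNA was extracted with a column kit and made into libraries with the TruSeq RNA kit, and single-end reads of 51 bases were obtained. The deposited count table holds raw read counts per gene symbol, as whole numbers with different totals per library. The deposited RPKM table holds the same counts scaled by the length of the gene model and by the library total, with no further factor. For all 20208 genes with an RPKM above 0, count and RPKM gave a gene length within 0.001 of a whole number. CASAVA 1.8.2, TopHat 1.3.3, featureCounts, edgeR and the hg19 build are named, per the submitters' processing notes, without their role or order. The annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense partners are uncertain.

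Libraries were grouped by the stage in the labels. The labels do not say whether the 3 replicates of a stage came from separate donors, so p-values measure only the spread between these samples, which may be technical. Pairs of libraries of the same stage differed by more than counting noise (chi-square per gene of 44.4 or more), so none was treated as 1 library deposited again, which does not show that they are independent samples.

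The counts were tested with edgeR 4.0.16 in R 4.3.3 by its robust quasi-likelihood F test with TMM factors and the filterByExpr filter, with all 9 libraries in 1 fit and stage as the only term. This left 16076 of 23368 gene symbols, of which 3160 in the table had no counts in any library. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The common biological coefficient of variation was 0.252. Contrasts were the 3 pairs of stages, the difference among all stages, and the difference between the 2 steps. Genes highest or lowest in BFUE, and genes that moved the same way at both steps, were those past the test at both steps.

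The 23 lists of genes, the test, the rule for named genes and most alternatives were fixed before the data were examined. Of 373 list entries 372 were found, 2 of them under an older symbol; ERFE was not analysed here. Lists with at least 5 tested members (22 of 23) were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The rule names the sort markers, up to 4 members of each list per comparison, all erythroid transcription factors and DNA methylation enzymes, and the 10 genes with the largest rise and fall per comparison among called genes with at least 10 CPM in the higher stage and no overlap between the libraries of the stages. It also names the 10 genes with the largest smaller change among those highest, and among those lowest, in BFUE. Some genes under this rule are not reported here. Symbols on the Y chromosome or with alleles that can mark a person (140) were kept out of all gene tables. Members that moved against their list, HBB and the other globin copies named, TFRC, the 5 granulocyte and monocyte markers that rose in CFUE, CSF1R, and markers of other myeloid lineages named as higher in BFUE outside the rule were chosen after their values were seen. Where a stage had no counts, a fold is a bound against 3 counts over the stage, and bounds cover counting error only.

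Replicate numbers were checked for pairing by correlating, across genes, the deviations of same-numbered libraries from their stage means. Between BFUE and CFUE the correlations were 0.399, 0.427 and 0.435, and each library correlated best with its own number, so these numbers were taken to pair the samples, from the data and not from the labels. Between HSPC and BFUE they were 0.119, 0.212 and −0.0218, and between HSPC and CFUE −0.110, 0.263 and −0.118, which pairs neither.

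The test was tested on simulated counts with these library sizes. For BFUE against HSPC, 0% of genes changed by 1.25-fold, 0% by 1.5-fold, 38% by 2-fold and 80% by 4-fold were recovered, with 6 of 15635 unchanged genes called. For CFUE against BFUE the shares were 0%, 2%, 32% and 68%, with 2 of 15637 unchanged genes called. Only 50 genes were changed at each fold, while 68.95% and 21.79% of genes were called in the 2 real comparisons. The adjustment is stricter where few genes change, so these shares do not apply to the reported tests. Alternatives were DESeq2 size factors, upper-quartile factors, no factors, no filter, a filter of 5 CPM in 3 libraries, a test against a 2-fold change, the replicate block, only the stages compared, library sizes without the 10 most abundant genes, DESeq2 1.42.0, limma-voom, limma on log2(RPKM + 0.5) or log2(RPKM + 0.05), fry, and leaving out each library. A GC correction, the block in BFUE and CFUE alone, the use of no factors the lists tested on the difference between steps, and the covariance of same-numbered libraries were added after the data had been seen. GC content came from an annotation of another build, matched by symbol for 94.8% of tested genes, and no coordinates are given.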

Results

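PolyA-selected RNA was sequenced from human umbilical cord cells at 3 stages of early red cell development, with 3 libraries per stage. HSPC libraries came from CD34+ hematopoietic stem and progenitor cells. BFUE libraries (burst-forming unit-erythroid, the earlier committed erythroid progenitor) came from cultured cells sorted as IL-3R−CD34+CD36−, and CFUE libraries (colony-forming unit-erythroid, the later progenitor) from cultured cells sorted as IL-3R−CD34−CD36+. The 9 libraries held between 50621417 and 78109606 counted reads over 23368 gene symbols. Principal component 1 held 76.1% of the variance of log2 CPM (read counts scaled by the effective library total with TMM factors). It separated all 3 stages, with BFUE between HSPC and CFUE. Its scores were −174.9 to −151.6 in HSPC, 42.4 to 61.4 in BFUE and 108.7 to 114.4 in CFUE. Component 2, with 13.5%, also separated BFUE from CFUE, with HSPC between them. The HSPC cells were not sorted from the erythroid culture, so stage, culture and sort differ together in every comparison with HSPC. Values below are mean CPM ± SD over 3 libraries. Changes are log2 fold changes with a standard error (SE) and Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test. The SE was derived as the absolute log2 fold change divided by the square root of that test's F. It is approximate, most of all for genes with few counts at a stage. Counts of list members were the same adjusted over the list alone unless a second count is given.

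**Figure D1:**
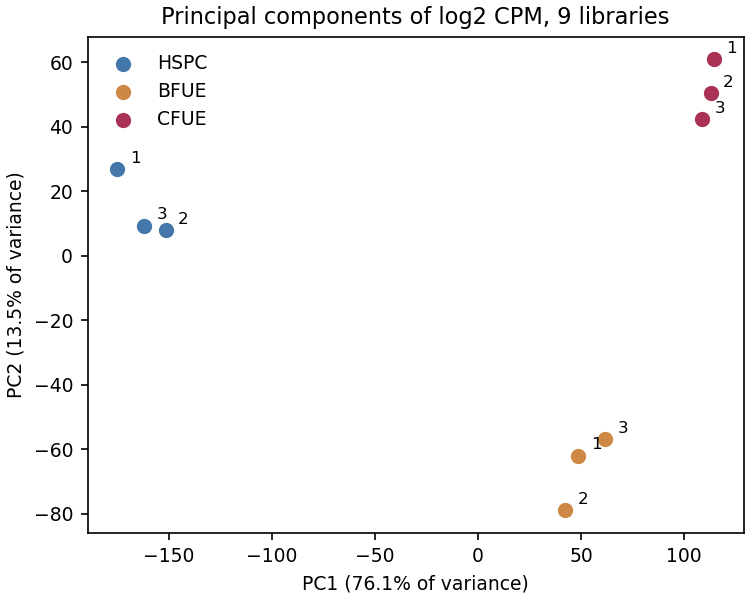
Each point is 1 library, labelled with its replicate number, on principal components 1 and 2 of log2 CPM (axes in component scores, with the percent of variance held). The 3 libraries of each stage lie together, HSPC at negative and BFUE and CFUE at positive scores of component 1, and BFUE at negative scores of component 2.

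The surface markers used for the sorts were measured at the RNA level first. BFUE and CFUE were sorted on opposite gates of CD34 and CD36. Their differences in these genes are therefore selected for by the sorts and are not a separate finding. CD34 was at 600.6 ± 109 CPM in HSPC, 139 ± 44.7 in BFUE and 2.43 ± 0.283 in CFUE. It fell at both steps (log2 fold change −2.12, SE 0.25, adjusted p = 5.45e-05 from HSPC to BFUE and −5.83, SE 0.30, adjusted p = 1.65e-05 from BFUE to CFUE). CD36 was at 19.0 ± 6.65 CPM in HSPC, 3.30 ± 0.531 in BFUE and 386 ± 46.7 in CFUE. It fell by 2.53 on the log2 scale at the first step and rose by 6.87 (SE 0.30, adjusted p = 1.62e-05) at the second. IL3RA, which encodes the IL-3 receptor alpha chain, had 2 counts over all 9 libraries and was not tested. It is a pseudoautosomal gene, and 17 of the 17 other pseudoautosomal protein-coding genes in the table were also under 1 CPM (scaled without TMM factors) in every library.

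The comparison of BFUE with HSPC asked which transcripts change between the CD34+ starting population and the earlier erythroid progenitor. Stem cell regulators and immediate early genes fell as lists, and genes of cell division, DNA replication, ribosome biogenesis and heme synthesis rose, by camera at its preset correlation but not with an estimated one (adjusted p from 0.253 to 0.580). Among transcription factors of stem and progenitor cells, HLF went from 79.1 ± 17.0 to 1.21 ± 0.678 CPM (log2 fold change −6.03, SE 0.56, adjusted p = 1.24e-05), and HOPX from 97.2 ± 12.6 to 2.46 ± 1.20 CPM (−5.31, SE 0.39, adjusted p = 3.26e-06). CRHBP, a marker of primitive progenitors, went from 99.2 ± 1.33 to 4.37 ± 2.33 CPM. Of the 30 stem and progenitor genes, 27 fell and 2 (HMGA2 and HOXB4) rose, HMGA2 without a call when HSPC replicate 1 (0.0718) or 2 (0.0718) or BFUE replicate 3 (0.0780) was left out; the list stood apart from the other tested genes (camera, adjusted p = 4.19e-06), and adjusted p = 0.378 with an estimated correlation.

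Proliferation genes moved together. All 20 mitosis genes were higher in BFUE (camera adjusted p = 1.15e-12), and adjusted p = 0.378 with an estimated correlation. TOP2A, the topoisomerase that untangles replicated chromosomes, rose from 13.8 ± 2.92 to 899.6 ± 57.0 CPM (log2 fold change 6.02, SE 0.19, adjusted p = 1.27e-07), and the mitotic kinase gene CDK1 from 4.80 ± 0.317 to 153 ± 28.6 CPM. All 22 DNA replication genes were higher as well (camera adjusted p = 3.58e-10, and adjusted p = 0.378 with an estimated correlation), with RRM2, a subunit of ribonucleotide reductase, at 18.1 ± 3.47 and 237.6 ± 62.3 CPM. Of 20 ribosome biogenesis genes, 15 rose and 2 (FBL and NOP58) fell (camera adjusted p = 2.36e-04, and adjusted p = 0.378 with an estimated correlation). Over 23 other settings FBL was called under 13 and NOP58 under 7. FBL lost its call without HSPC replicate 1 or 3 or BFUE replicate 1 or 2 (0.0514 to 0.113), and NOP58 without HSPC replicate 1 or 2, any BFUE replicate or CFUE replicate 1 or 2 (0.0594 to 0.257). MYC rose from 66.6 ± 15.1 to 472 ± 58.1 CPM and POLR1A, the largest subunit of RNA polymerase I, from 34.3 ± 1.91 to 150.5 ± 17.5 CPM.

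Among 15 erythroid transcription factors, 7 rose from HSPC to BFUE (8 adjusted over the list alone) and 6 fell, and the list as a whole was not called (camera adjusted p = 0.488). KLF1 rose from 7.24 ± 3.05 to 61.9 ± 10.99 CPM (log2 fold change 3.09, SE 0.35, adjusted p = 4.50e-05). GATA1 rose from 38.4 ± 7.93 to 139.9 ± 24.1 CPM (1.87, SE 0.20, adjusted p = 3.09e-05) and GFI1B from 14.5 ± 5.13 to 58.6 ± 1.54 CPM. TAL1, LDB1, NFE2 and E2F2 were the other members that rose. KLF3, FOXO3, BCL11A, SOX6, LMO2 and IKZF1 were lower. The call of SOX6 was lost without HSPC replicate 1 (adjusted p = 0.0560), that of IKZF1 without HSPC replicate 1 or any of the BFUE replicates (0.0725 to 0.135), and that of LMO2 without any library other than HSPC replicate 2 (0.0502 to 0.184). MYB was at 550.5 ± 68.5 and 575.9 ± 134 CPM, which was not past the threshold. ZFPM1 was at 5.21 ± 3.01 and 14.7 ± 2.35 CPM and missed it (adjusted p = 0.0508). It was called higher under 13 of 23 other settings, among them DESeq2 (0.0105), the replicate block (0.0414), the 2 stages alone (0.0153) and leaving out HSPC replicate 2 (0.0482), CFUE replicate 2 (0.0345) or CFUE replicate 3 (0.0107), with a range of 2.73e-04 to 0.233 over all of them. LMO2 was called under 7, IKZF1 under 13 of 23 and SOX6 under 17 of 21. Heme synthesis genes rose in 8 of 11 cases and fell in none, or in 1 without HSPC replicate 3 or BFUE replicate 3 (camera adjusted p = 0.0335, and adjusted p = 0.580 with an estimated correlation). FECH, the ferrochelatase that inserts iron to form heme, went from 34.4 ± 1.12 to 104 ± 11.1 CPM and CPOX from 23.5 ± 2.80 to 82.6 ± 14.4 CPM. The iron list had 8 of 12 genes higher and 3 lower (camera adjusted p = 0.139). The transferrin receptor gene TFRC was at 399 ± 69.7 and 1416 ± 505 CPM, and the ferritin heavy chain gene FTH1 fell from 3364 ± 1259 to 606 ± 67.2 CPM. The red cell membrane list had 13 of 25 genes higher and 4 lower (camera adjusted p = 0.0839), including RHAG at 3.84 ± 0.498 and 33.7 ± 11.1 CPM. Of the 11 globin list members, HBD, HBE1 and HBQ1 rose and 6 fell (camera adjusted p = 0.488). The call of HBQ1 was lost without HSPC replicate 1 (0.0753) or 2 (0.0589) or BFUE replicate 2 (0.0540). HBD went from 5.86 ± 2.17 to 142 ± 56.3 CPM. Late erythroid genes (7 higher and 5 lower of 17, with 7 lower adjusted over the list alone and 3 without BFUE replicate 2) and genes of erythropoietin and KIT signalling (4 higher and 4 lower of 13) were not called as lists (camera adjusted p = 0.724 and 0.949). The test pointed up for both, while the late erythroid list had a median log2 change of −0.19 and the signalling list a mean of −0.12. SOCS3 fell from 44.5 ± 16.4 to 2.56 ± 0.573 CPM and CISH rose from 10.7 ± 4.06 to 46.5 ± 12.2 CPM, both feedback inhibitors of cytokine signalling.

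Markers of other blood lineages split in BFUE. Granule proteins of eosinophils rose, EPX from 10.7 ± 4.43 to 617 ± 207 CPM (log2 fold change 5.85, SE 0.59, adjusted p = 2.02e-05) and PRG2 from 74.4 ± 40.6 to 1355 ± 453 CPM. Of the 11 mast cell, basophil and eosinophil markers 7 rose and none fell (camera adjusted p = 0.0369, and adjusted p = 0.540 with an estimated correlation). Of 19 granulocyte and monocyte markers 7 rose and 8 fell (camera adjusted p = 0.697). The risers included CTSG (9.78 ± 0.833 to 74.9 ± 24.5 CPM) and PRTN3 (9.58 ± 4.92 to 147 ± 142 CPM), which encode granule proteases. The genes that fell included S100A8 (261 ± 141 to 0.127 ± 0.130 CPM) and S100A9 (436 ± 117 to 0.480 ± 0.180 CPM), abundant transcripts of mature neutrophils and monocytes. Lymphoid markers fell in 12 of 17 cases and rose in 2 (camera adjusted p = 0.0156, and adjusted p = 0.468 with an estimated correlation). A single marker rose without HSPC replicate 1, HSPC replicate 3 or any BFUE replicate, and both calls were lost without HSPC replicate 2. Endothelial and stromal markers fell in 8 of 12 (camera adjusted p = 0.0191, and adjusted p = 0.378 with an estimated correlation) and MHC class II genes in 7 of 8 (0.0407, and adjusted p = 0.616 with an estimated correlation). The endothelial and extracellular matrix transcripts stood highest in HSPC replicate 1. VWF was at 164 CPM there and at 20.6 and 29.1 CPM in the other HSPC libraries, and MGP at 138, 3.92 and 7.39 CPM. Megakaryocyte and platelet markers fell in 9 of 14 cases and rose in 2, without a call for the list (camera adjusted p = 0.139), and 1 rose without HSPC replicate 2 or 3 or BFUE replicate 3. ITGA2B rose from 34.5 ± 6.41 to 294 ± 56.3 CPM.

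Immediate early and stress response transcripts were abundant in HSPC. NR4A1 fell from 1574 ± 525 to 1.27 ± 0.193 CPM (log2 fold change −10.27, SE 0.37, adjusted p = 1.27e-07), ZFP36 from 1149 ± 202 to 5.68 ± 0.364 CPM and JUN from 1039 ± 124 to 5.60 ± 7.47 CPM. Of 15 immediate early and heat shock genes 13 fell and 1, HSPH1, rose (camera adjusted p = 2.36e-04, and adjusted p = 0.253 with an estimated correlation). Interferon response genes fell in 8 of 14 cases and rose in 1, or 2 without HSPC replicate 1 (camera adjusted p = 0.0948). Cholesterol synthesis genes went both ways, 6 higher and 6 lower of 16 (camera adjusted p = 0.954, with a median of −0.34 where the test pointed up).

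Enzymes and readers of DNA methylation changed gene by gene. DNMT1, the maintenance methyltransferase, rose from 115 ± 22.3 to 445.5 ± 48.8 CPM (log2 fold change 1.96, SE 0.17, adjusted p = 7.89e-06), and its partner UHRF1 from 43.8 ± 13.8 to 223 ± 43.8 CPM (2.35, SE 0.24, adjusted p = 2.47e-05). The de novo methyltransferase gene DNMT3B rose from 83.8 ± 11.2 to 148 ± 9.51 CPM (0.82, SE 0.17), while DNMT3A was at 94.4 ± 12.4 and 78.3 ± 15.8 CPM (adjusted p = 0.228). MBD4, MBD1 and ZBTB38 also rose. TET2, which oxidises 5-methylcytosine, fell from 112 ± 22.0 to 68.1 ± 4.87 CPM (−0.72, SE 0.14, adjusted p = 0.00133), and ZBTB4 fell. MBD2, MBD3, TDG, TET1, TET3 and UHRF2 had adjusted p between 0.121 and 0.723. With upper-quartile factors DNMT3A (0.0248), MBD2 (0.0150), TET3 (0.00523) and UHRF2 (0.00686) passed the threshold. TDG passed under 4 of 23 other settings, 1 of them without HSPC replicate 1 (0.0334), UHRF2 also without HSPC replicate 3 (0.0146), and MBD3 with the GC correction (0.0222). The list of 16 genes was not called (6 higher, 3 lower, camera adjusted p = 0.488). Neither were the 30 histone modifying enzymes (12 higher, 11 lower, adjusted p = 0.751, median log2 change 0.09 and mean −0.03). Among the latter, EED rose from 6.42 ± 1.45 to 42.2 ± 5.66 CPM and KDM6B fell from 283 ± 72.9 to 32.7 ± 2.95 CPM.

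Of 16076 genes tested, 5261 were higher and 5823 lower in BFUE than in HSPC, 3121 and 4566 of them by at least 2-fold. The genes with the largest rise were PSAT1, a serine synthesis enzyme (1.10 ± 0.0812 to 376 ± 122 CPM), CTTNBP2, CBS, SIGLEC6 and GPR85. AREG had no counts in BFUE and was at least 813-fold lower there (3 counts over the stage taken as the floor). The share of calls that were higher was 47.5% with TMM factors and 36.6% with upper-quartile factors (4055 higher, 7028 lower), so the balance of higher and lower genes is not fixed by these data. Tested against a 2-fold change, 2077 genes were higher and 3210 lower.

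**Figure D2:**
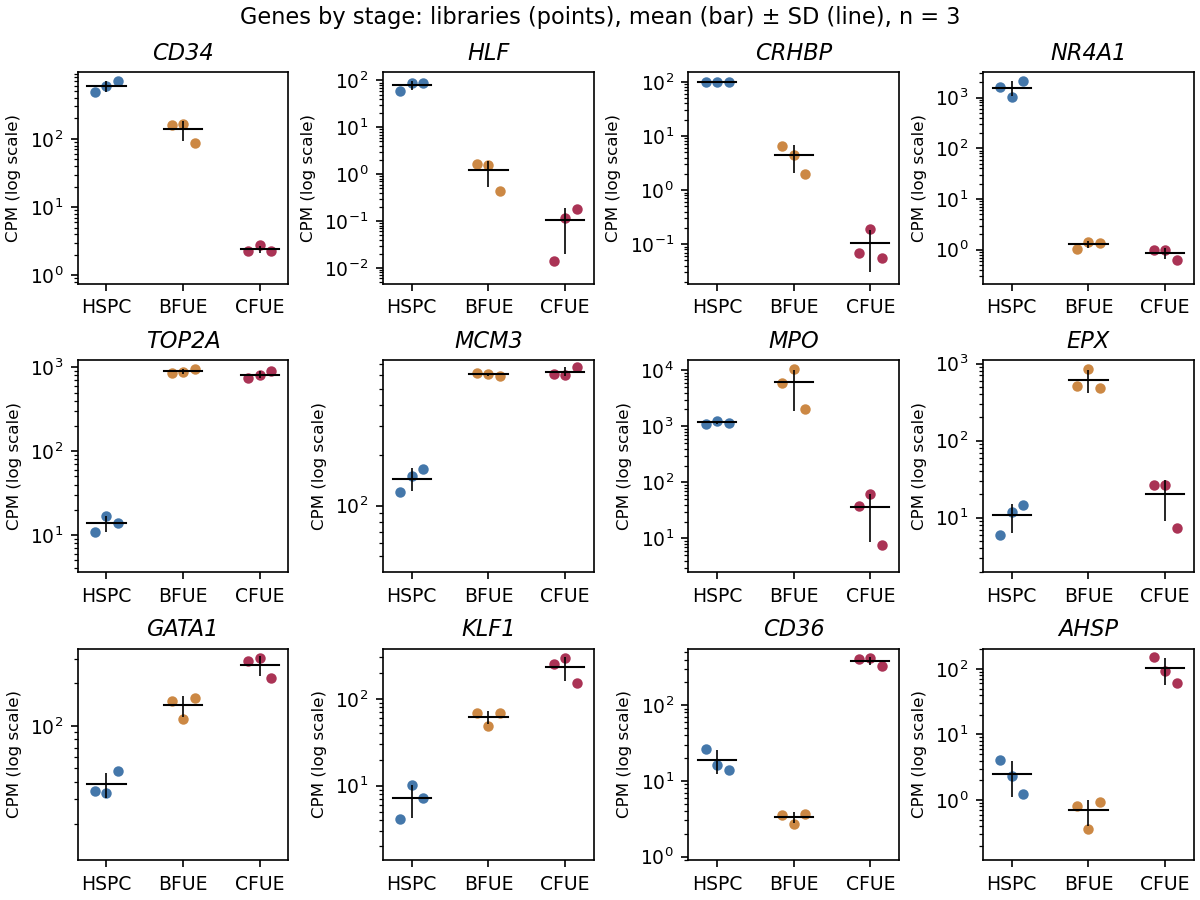
CPM (log axis) of 12 genes in each of the 9 libraries by stage; points are libraries, horizontal bars the stage means and vertical lines ± 1 SD (n = 3). CD34, HLF and CRHBP fall at both steps, TOP2A and MCM3 differ between HSPC and both later stages, MPO and EPX are highest in BFUE (6101 and 617 CPM on average), and GATA1 and KLF1 rise at both steps.

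The comparison of CFUE with BFUE followed the step between the 2 sorted erythroid progenitors. Globin, heme synthesis and red cell membrane genes rose as lists, and stem and progenitor, lymphoid and mast cell, basophil and eosinophil genes fell, by camera at its preset correlation but not with an estimated one (adjusted p from 0.147 to 0.266). Of 20 mitosis genes 1 passed the test, and of 22 DNA replication genes none did. AHSP, the chaperone of alpha-globin, rose from 0.699 ± 0.296 to 101.1 ± 45.1 CPM (log2 fold change 7.18, SE 0.59, adjusted p = 7.49e-05), and SPTB, which encodes erythroid beta-spectrin, from 3.57 ± 0.818 to 144 ± 57.9 CPM (5.33, SE 0.39, adjusted p = 5.03e-05). MPO fell from 6101 ± 4213 to 35.9 ± 27.4 CPM (−7.41, SE 0.90, adjusted p = 4.25e-04).

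Of the 11 globin list members 9 rose (10 adjusted over the list alone) and none fell (camera adjusted p = 7.10e-08, and adjusted p = 0.147 with an estimated correlation). HBA1 went from 0.681 ± 0.0878 to 21.6 ± 11.8 CPM and HBA2 from 0.0789 ± 0.0316 to 7.38 ± 5.79 CPM; their near-identical sequences make the split between these copies uncertain, as it is for HBG1 and HBG2. HBB was at 124 ± 94.9 and 891 ± 587 CPM, an increase in the mean that did not pass the test (adjusted p = 0.0543). It passed under 11 of 25 other settings (0.00529 to 0.200 over all), among them DESeq2 (0.00789), the replicate block (0.00754), and leaving out HSPC replicate 1 (0.0488) or 3 (0.0227), BFUE replicate 1 (0.0489) or CFUE replicate 3 (0.0319). Heme synthesis genes rose in 10 of 11 cases (camera adjusted p = 8.08e-08, and adjusted p = 0.147 with an estimated correlation). ALAS2, the erythroid rate-limiting enzyme, was at 6.48 ± 4.13 and 65.0 ± 10.8 CPM and UROD at 157 ± 34.9 and 383 ± 28.6 CPM. Of 25 membrane and blood group genes 18 rose and 2 (BCAM and CD44) fell (camera adjusted p = 5.04e-08, and adjusted p = 0.266 with an estimated correlation). EPB42 rose from 2.18 ± 1.02 to 33.3 ± 13.8 CPM. Of 17 late erythroid genes 10 rose, 11 adjusted over the list alone, and 1 fell without BFUE replicate 3 (camera adjusted p = 2.88e-06, and adjusted p = 0.147 with an estimated correlation), CA2 from 0.890 ± 0.0946 to 19.7 ± 5.98 CPM and SELENBP1 from 1.95 ± 1.04 to 26.2 ± 4.81 CPM. Iron genes rose in 5 of 12 cases, 7 adjusted over the list alone and 3 without BFUE replicate 2 or CFUE replicate 1 (camera adjusted p = 1.45e-04, and adjusted p = 0.147 with an estimated correlation). STEAP3 rose from 51.9 ± 11.3 to 108 ± 14.7 CPM and the mitochondrial iron importer SLC25A37 from 19.1 ± 0.847 to 40.05 ± 9.12 CPM. Genes of erythropoietin and KIT signalling rose in 5 of 13 cases, 3 without CFUE replicate 1, and 1 fell without CFUE replicate 3 (camera adjusted p = 0.0269, and adjusted p = 0.307 with an estimated correlation). The erythropoietin receptor gene EPOR rose from 19.2 ± 1.86 to 69.8 ± 26.8 CPM and JAK2 from 26.9 ± 1.60 to 53.1 ± 9.31 CPM.

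Among the 15 erythroid transcription factors 7 rose (9 adjusted over the list alone) and none fell (camera adjusted p = 3.65e-04, and adjusted p = 0.157 with an estimated correlation). KLF1 rose from 61.9 ± 10.99 to 232 ± 73.6 CPM (log2 fold change 1.91, SE 0.33, adjusted p = 0.00278). GATA1 rose from 139.9 ± 24.1 to 269.5 ± 45.4 CPM (0.95, SE 0.19, adjusted p = 0.00670), GFI1B from 58.6 ± 1.54 to 156 ± 43.7 CPM and LMO2 from 134 ± 16.4 to 316 ± 32.9 CPM. KLF3 and LDB1 rose too, and so did SOX6, whose call was lost without HSPC replicate 2, BFUE replicates 2 and 3 and CFUE replicates 1 and 2 (adjusted p between 0.0617 and 0.154). NFE2, MYB, BCL11A, IKZF1, ZFPM1, TAL1, FOXO3 and E2F2 were not called. With the replicate number as a block, in a fit of BFUE and CFUE alone, TAL1 (adjusted p = 0.0490) and FOXO3 (0.0136) were called higher and E2F2 (0.0176) lower. Over 25 other settings FOXO3 was called under 14 (adjusted p from 0.00964 to 1, and 0.0519 in the reported fit), TAL1 under 5, E2F2 under 4 and ZFPM1 under 2. With 1 library left out, calls came without HSPC replicate 1 (0.0256) or 2 (0.0122) for FOXO3, without BFUE replicate 3 (0.0487) for TAL1, and without CFUE replicate 3 for E2F2 (0.0224) and ZFPM1 (0.0385).

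Stem and progenitor genes fell again, 23 of 30, with 1 higher only when adjusted over the list alone (camera adjusted p = 7.90e-11, and adjusted p = 0.147 with an estimated correlation). PROM1 went from 26.3 ± 14.99 to 0.207 ± 0.0497 CPM and BAALC from 9.66 ± 3.91 to 0.0803 ± 0.0457 CPM. Of the mast cell, basophil and eosinophil markers 9 of 11 fell, and 2 rose when CFUE replicate 3 was left out (camera adjusted p = 7.65e-06, and adjusted p = 0.147 with an estimated correlation), CPA3 from 343 ± 90.8 to 15.3 ± 6.71 CPM. Of the granulocyte and monocyte markers 11 of 19 fell (12 adjusted over the list alone) and 5 rose (camera adjusted p = 0.0188, and adjusted p = 0.307 with an estimated correlation). The 5 that rose were LYZ, S100A8, S100A9, FCN1 (not called without BFUE replicate 1, 0.0650) and CD14, and in the same direction VCAN rose from 0.400 ± 0.00818 to 18.3 ± 4.02 CPM. Of the 5, S100A8 rose only to 1.05 ± 0.272 CPM in CFUE, against 261 ± 141 CPM in HSPC. CLEC10A and CD1C, markers of dendritic cells, rose mainly in CFUE replicate 3, at 49.3 and 30.7 CPM against 7.55 or less and 1.66 or less in the other CFUE libraries. The call of CD1C was lost without that library (adjusted p = 0.123), as it was without BFUE replicate 1 (0.104), BFUE replicate 2 (0.103) or HSPC replicate 2 (0.0503). Lymphoid markers fell in 12 of 17 cases, 14 adjusted over the list alone (camera adjusted p = 1.47e-07, and adjusted p = 0.147 with an estimated correlation). MHC class II genes fell in 2 of 8, 4 adjusted over the list alone (camera adjusted p = 0.0134, and adjusted p = 0.414 with an estimated correlation). Both calls were lost without BFUE replicate 1, CFUE replicate 1 or CFUE replicate 2, while 1 fell without BFUE replicate 3 and 6 without CFUE replicate 3. MZB1 fell from 13.7 ± 9.98 to 0.0376 ± 0.0301 CPM.

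Ribosome biogenesis genes rose in 5 of 20 cases, 6 adjusted over the list alone (camera adjusted p = 1.45e-04, and adjusted p = 0.271 with an estimated correlation), WDR12 from 83.3 ± 6.55 to 134 ± 15.9 CPM. The 5 became 2 without BFUE replicate 1 or 2 or CFUE replicate 1 or 3, and 3 without BFUE replicate 3 or CFUE replicate 2. None of 22 DNA replication genes and 1 of 20 mitosis genes (NUSAP1, none adjusted over the list alone) passed the test (camera adjusted p = 0.711 and 0.915). At an unadjusted p under 0.05 edgeR called 1 replication gene, DESeq2 called 1 after adjustment and limma-voom 0. All of these fits left out the pairing of the replicate numbers. The block fit of BFUE and CFUE alone called 5512 genes, against 3663 without the block. Called members of whole lists were not counted in it, so these small counts hold for the unpaired fits only. MCM3 was at 607 ± 13.5 and 630 ± 39.2 CPM and MKI67 at 682 ± 84.1 and 585 ± 161 CPM. The call of NUSAP1 was lost without any library other than HSPC replicate 1 and CFUE replicate 3 (adjusted p between 0.0526 and 0.193). Lists without a call were also the endothelial and stromal markers (3 of 12 lower, camera adjusted p = 0.0748), megakaryocyte and platelet markers (1 higher and 2 lower of 14, with 3 higher without CFUE replicate 3, 0.676), and cholesterol synthesis (0 of 16 by edgeR, DESeq2 and limma-voom, with 1 at an unadjusted p under 0.05 and 1 called without HSPC replicate 1 or BFUE replicate 3, 0.815). Nor was there a call for interferon response (3 of 14 lower, 4 adjusted over the list alone, 0.230), immediate early and heat shock genes (1 of 15 lower, 0.802) or histone modifying enzymes (2 higher and 1 lower of 30, with 1 higher adjusted over the list alone, 0.189). Without BFUE replicate 2 or CFUE replicate 1 the 3 interferon genes became 1, and the immediate early gene lost its call without either of these or BFUE replicate 1. An interferon gene was higher without BFUE replicate 1 or CFUE replicate 3. The immediate early gene ZFP36 was higher without HSPC replicate 1 (0.04999) or 3 (0.0352), and by DESeq2 (0.0338). Of the histone genes 1 was higher without HSPC replicate 1 or 2, BFUE replicate 1 or 2 or CFUE replicate 1, and 2 were lower without CFUE replicate 2. Of the 16 DNA methylation genes, DNMT3A fell from 78.3 ± 15.8 to 36.2 ± 6.54 CPM (log2 fold change −1.11, SE 0.19, adjusted p = 0.00262) and DNMT3B from 148 ± 9.51 to 83.1 ± 18.7 CPM (−0.83, SE 0.17, adjusted p = 0.00675), while DNMT1 was at 445.5 ± 48.8 and 446 ± 43.6 CPM. ZBTB4 and ZBTB38 rose and TET2 fell (−0.52, SE 0.14, adjusted p = 0.0269); TET2 lost its call without each BFUE or CFUE library (adjusted p between 0.0551 and 0.117), and ZBTB38 without each of them and without HSPC replicate 2 (0.0516 to 0.150). The list was not called (camera adjusted p = 0.697, median log2 change 0.13 and mean −3.45e-04). UHRF1 (adjusted p = 0.182) was lower with the replicate block in BFUE and CFUE alone (0.0150) and without HSPC replicate 1 (0.0400). TET3 was called under 4 of 25 other settings, 1 of them without CFUE replicate 3 (0.0479).

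**Figure D3:**
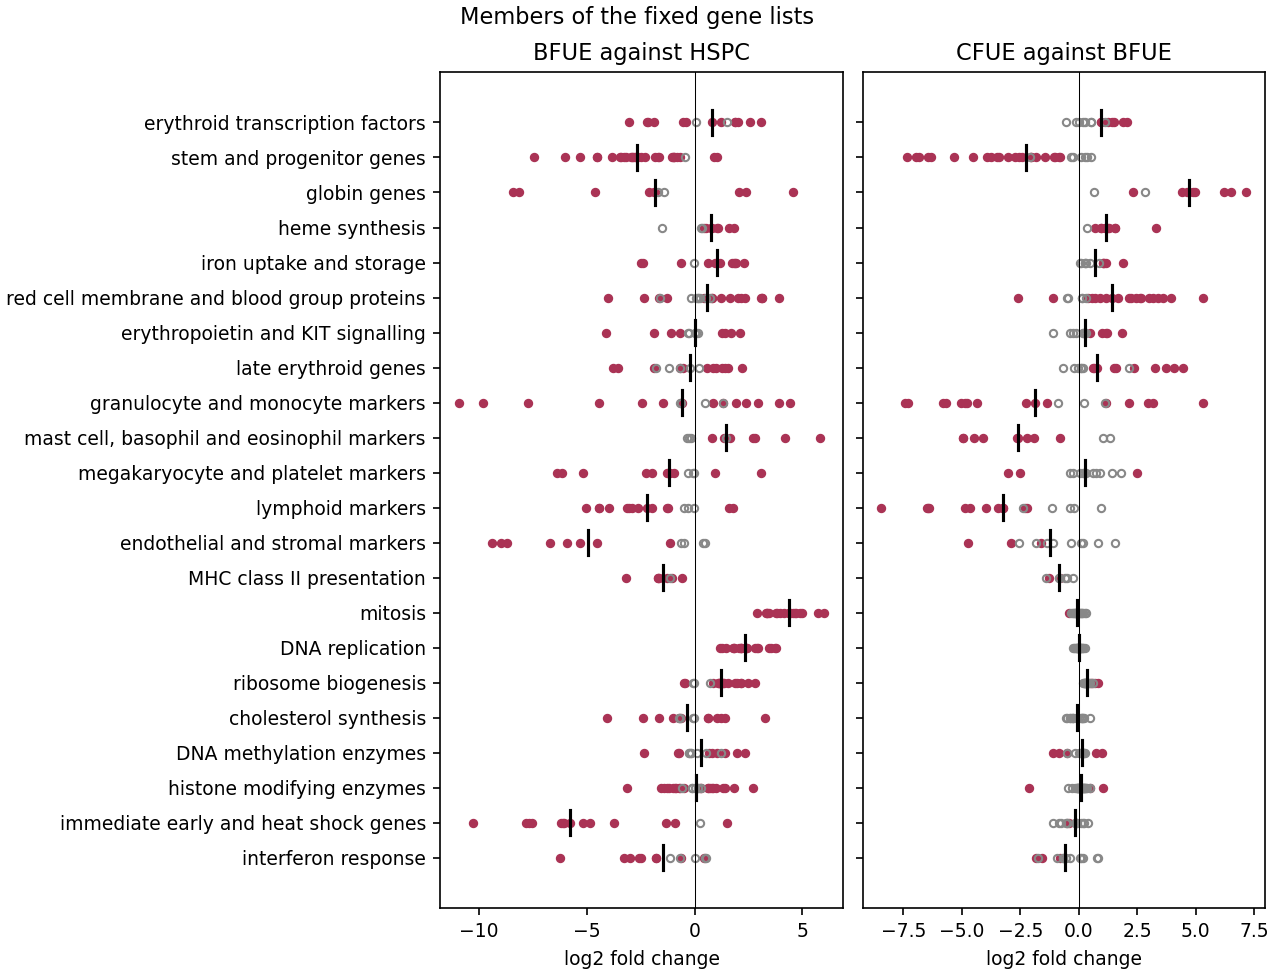
Log2 fold change (horizontal axis) of every tested member of the 22 fixed lists with at least 5 tested members, at the step from HSPC to BFUE (left) and from BFUE to CFUE (right); filled points passed the gene test, open points did not, and black bars are list medians. The mitosis and DNA replication lists lie above 0 at the left (medians 4.38 and 2.35) and near 0 at the right (−0.06 and 0.01), and the globin list lies above 0 at the right (4.73); fitted changes of members with few counts at a stage depend on the prior count.

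In all, 1329 genes were higher and 2174 lower in CFUE than in BFUE, 679 and 1666 of them by at least 2-fold. The genes with the largest falls also included SLC2A5, CEBPE and HGF, and those with the largest rises GALNT5 (0.289 ± 0.0524 to 30.03 ± 9.76 CPM) and DOCK9. With the replicate number as a block in a fit of BFUE and CFUE alone, 2599 genes were higher and 2913 lower, against 1530 and 2133 in the same libraries without the block, and with a GC correction added 3027 and 3273. The GC correction alone gave 2210 higher and 2151 lower, which moved the share that was higher from 37.9% to 50.7%. The count of higher genes fell to 751 without BFUE replicate 2 and to 855 without CFUE replicate 1.

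**Figure D4:**
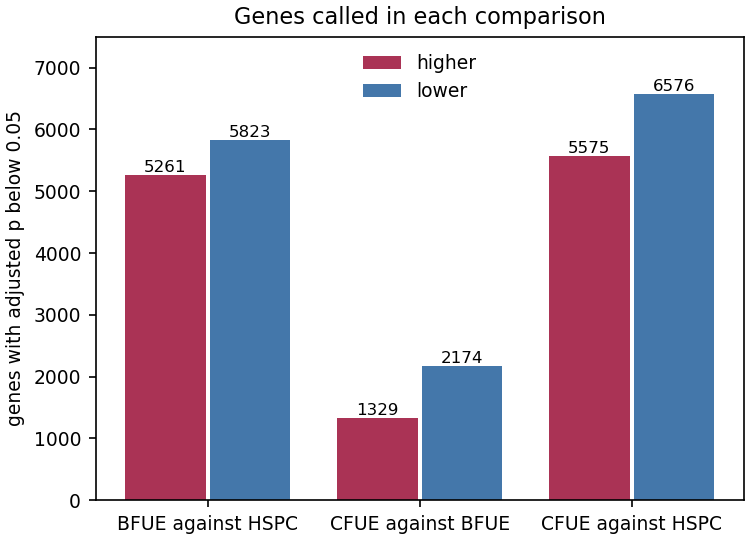
Number of genes with an adjusted p below 0.05 (vertical axis, from 0) that were higher or lower in each of the 3 comparisons of stages. The numbers called in either direction were 11084 for BFUE against HSPC, 3503 for CFUE against BFUE and 12151 for CFUE against HSPC.

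The comparison of CFUE with HSPC spanned both steps. Of 16076 genes, 5575 were higher and 6576 lower in CFUE, 3676 and 5406 of them by at least 2-fold, and with upper-quartile factors 4325 were higher and 7730 lower (35.9% of calls higher, against 45.9%). PKLR, the red cell pyruvate kinase gene, went from 1.42 ± 0.557 to 180 ± 68.7 CPM (log2 fold change 6.98, SE 0.52, adjusted p = 2.28e-06), and CDH1, which encodes E-cadherin, from 1.07 ± 0.423 to 365 ± 218 CPM (8.40, SE 0.97, adjusted p = 3.38e-05). The embryonic globin gene HBE1 rose from 0.201 ± 0.0391 to 31.5 ± 22.98 CPM. AQP9, C1QTNF4 and CLEC14A had no counts in CFUE and were at least 4001-fold, 1258-fold and 834-fold lower there. All 11 heme synthesis genes (camera adjusted p = 2.41e-04), 20 of 20 mitosis genes (3.01e-11), 22 of 22 DNA replication genes (3.71e-09) and 16 of 20 ribosome biogenesis genes (2.88e-05) were higher. So were 19 of 25 membrane genes (4 lower, 3.20e-04) and 10 of 17 late erythroid genes (2 lower, 0 or 1 with any 1 library left out, 0.00887). The same held for 8 of 12 iron genes (2 lower, 0.0155) and 7 of 11 globin list members (1 lower, 0 to 2 with 1 library left out, 0.0338). With an estimated correlation these lists had an adjusted p of 0.217, except the iron (0.290), membrane (0.407) and globin (0.428) lists. Lower were 28 of 30 stem and progenitor genes (1 higher, or 2 without HSPC replicate 3, BFUE replicate 1 or CFUE replicate 1, camera adjusted p = 5.54e-08). So were 14 of 17 lymphoid (2.55e-04), 13 of 15 immediate early (1 higher, 5.42e-04) and 11 of 12 endothelial and stromal genes (0.00193). The rest were 14 of 19 granulocyte and monocyte (1 higher, 0 without HSPC replicate 2 or 3 or CFUE replicate 1 or 3, 0.00339) and 8 of 8 MHC class II genes (0.0112). With an estimated correlation their adjusted p was 0.217, and 0.424 for MHC class II. Adjusted over the list alone, 5 membrane genes were lower in place of 4, and 1 lymphoid gene was higher. DNMT3A was lower in CFUE than in HSPC (−1.38, SE 0.19, adjusted p = 1.17e-04), DNMT3B was at 83.8 ± 11.2 and 83.1 ± 18.7 CPM, and UHRF1 was higher (1.87, SE 0.24). The erythroid transcription factors (9 higher, 4 lower of 15, camera adjusted p = 0.0586) were not called. Neither were the interferon (adjusted p = 0.0725), erythropoietin and KIT (0.186), megakaryocyte (0.324), DNA methylation (0.347), histone (0.383), mast cell (0.668, with a median log2 change of 0.16 where the mean was −0.56 and the test pointed down) and cholesterol (0.992) lists.

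Across the 3 stages, 12650 of the 16076 genes differed. The log2 change differed between the steps for 7106 genes, among them all 20 mitosis genes and 21 of 22 DNA replication genes, which had risen from HSPC to BFUE, and CD36 and AHSP, which rose after BFUE. The gates of the sorts select for the rise of CD36 and for its low level in BFUE. Expression was highest in BFUE for 463 genes and lowest there for 316, while 621 rose and 1000 fell at both steps. The 10 genes that ranked highest in BFUE by the smaller of their 2 changes were EPX, CEBPE, RNASE2, FBN2, PRTN3, P2RY2, DHRS9, SERPINB10, CTSG and SIGLEC12. CEBPE, a transcription factor of late granulocyte maturation, was at 0.749 ± 0.417, 16.5 ± 13.9 and 0.101 ± 0.0579 CPM, and RNASE2, an eosinophil granule ribonuclease gene, at 5.95 ± 1.42, 109 ± 38.8 and 2.18 ± 0.937 CPM in the stages in order. Lowest in BFUE were VCAN, HBA1, CA2, OPTN, CD36, LGALS3BP, MXD1, REPS2, JHDM1D and IFI30. CA2, carbonic anhydrase 2, was at 10.6 ± 2.29, 0.890 ± 0.0946 and 19.7 ± 5.98 CPM.

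Both steps share the BFUE libraries, so their chance values are linked. Unchanged genes simulated with these library sizes, as independent libraries, gave a mean correlation of −0.499 between the log2 changes of the 2 steps across genes and no gene called at both, against an observed correlation of 0.09. The covariance was 0.22 observed and −0.07 simulated, a difference of 0.28. The simulation leaves out that same-numbered BFUE and CFUE libraries deviate together. It also changes no gene at either step, while 68.95% and 21.79% of genes were called in the data. It therefore cannot tell how many genes changed at 1 step were called at the other through the shared BFUE libraries. From the spread of log2 CPM within stages the covariance with no change was −0.0512 for independent libraries and −0.0259 when the covariance of the same-numbered ones was added, a difference of 0.244 from the observed value. Independent lists of the same sizes would share 711.5 genes highest in BFUE, 481.4 lowest, 434.9 higher at both steps and 787.5 lower at both. Without BFUE replicate 2 the numbers highest and lowest in BFUE were 282 and 149 and the number higher at both steps 339, and without BFUE replicate 1 the last was 371, with 188 lowest and 651 lower at both. Without CFUE replicate 1, 206 genes were lowest in BFUE and 367 higher at both steps.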

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

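The GC correction, the replicate block in BFUE and CFUE alone and the use of no scaling factors were chosen after the results had been seen; the other settings were planned. Of the named gene values under 25 settings, 9749 kept their side of the threshold, 266 were no longer called (62 of them in the test against a 2-fold change) and 109 became called. Among values called in the reported fit or in the setting, 0 reversed direction. A change of sign in values called in neither was not counted. Causes were not tested except where a setting tests fewer genes or libraries or a larger fold.

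With upper-quartile factors 391 genes were higher at both steps. The filter of 5 CPM, which tests 10913 genes, left 3707 lower in BFUE and 4076 lower in CFUE than in HSPC, and 286 highest in BFUE. The test against a 2-fold change called 2077 higher and 3210 lower in BFUE than HSPC, 302 and 952 in CFUE against BFUE, 2754 and 4241 in CFUE against HSPC, 3000 for the step difference, 85 highest and 76 lowest in BFUE, and 41 higher and 319 lower at both steps. The GC correction called 2210 higher in CFUE than BFUE and 1202 higher at both steps. DESeq2 called 2002 and 991. The RPKM values with a pseudocount of 0.5 gave 159 lowest in BFUE and 607 lower at both steps. With no factors, 6127 genes were higher and 4979 lower in BFUE than in HSPC, and the median log2 change of all genes was 0.14, against −0.08 with TMM and −0.37 with upper-quartile factors.

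With the replicate block in BFUE and CFUE alone, 2599 genes were higher in CFUE than BFUE (2913 lower), and with the GC correction 3027 higher and 3273 lower. In the same libraries without the block it was 1530 and 2133, and 3618 of these 3663 genes were called with it, all in the same direction. In the fit of all 9 libraries the block gave 1398 and 2254, and it moved no other count of genes or lists by over 1.5 times.

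Lists called by camera numbered 10, 13 and 14 in BFUE against HSPC, CFUE against BFUE and CFUE against HSPC. With an estimated correlation camera called 0, 0 and 0, with 1, 7 and 1 at an unadjusted p under 0.05, and fry called 18, 15 and 21. The GC correction was not run on the lists.

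Leaving out each library gave 5037 to 5650 genes higher and 5053 to 6179 lower in BFUE than HSPC, 751 to 1474 and 1583 to 2285 in CFUE against BFUE, and 5371 to 5970 and 6244 to 6689 in CFUE against HSPC. It gave 12161 to 13120 differing among stages, 5144 to 7492 for the step difference, 282 to 547 highest and 149 to 375 lowest in BFUE, and 339 to 675 higher and 651 to 992 lower at both steps. The lowest counts of 751, 282, 149 and 339 came without BFUE replicate 2, and that of 651 without BFUE replicate 1. Lists called ranged over 9 to 10, 11 to 14 and 13 to 15.

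Depth limits the statements on scarce transcripts, since a count of 0 over a stage allows up to 3 counts. This floor covers counting error only, and not genes whose reads were left uncounted for other reasons.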

Other observations

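All tests in this part were chosen after the results had been seen, except the counts of splits. Genes for ribosomal proteins, the structural proteins of the ribosome, fell from HSPC to BFUE in 76 of 81 cases and rose in 3. Their median log2 change was −1.16 and lay between −0.92 and −1.45 over the scalings tried. In CFUE against BFUE edgeR called 0 of them (7 at an unadjusted p under 0.05), DESeq2 1 and limma-voom 0, all without the replicate block. They held 20.2 ± 2.05% of counts in HSPC, 10.4 ± 0.438% in BFUE and 9.24 ± 0.402% in CFUE (SD, n = 3). Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose in 18 of 20 cases from HSPC to BFUE (median 1.60, and 1.31 to 1.82 over the scalings) and fell in 1. All 12 genes of serine and one-carbon synthesis rose (median 2.49, and 2.20 to 2.71). That set includes PSAT1 and CBS, ranked among the largest rises in BFUE. Its count therefore partly restates that ranking and is not separate support.

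Of 10 genes typical of monocytes and dendritic cells, 6 fell and 0 rose from HSPC to BFUE (median −2.58, and −2.36 to −2.87 over the scalings). From BFUE to CFUE 9 rose (median 5.31, and 5.26 to 5.38), and in CFUE against HSPC 2 were higher and 2 lower (median 0.386, and 0.0466 to 0.601). The set was drawn up after the results were seen. It includes CLEC10A, VCAN and CD1C, ranked among the largest rises in CFUE, and LGALS3BP and IFI30, ranked among the lowest in BFUE. Its counts therefore partly restate those rankings and are not separate support. CSF1R, the receptor of a monocyte growth factor, was at 32.8 CPM in CFUE replicate 3 and at 6.82 and 5.23 CPM in the other CFUE libraries, and was not called (adjusted p = 0.228).

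IL3RA had 2 counts over all libraries. Of the 17 other pseudoautosomal protein-coding genes in the table, 17 were under 1 CPM (scaled without TMM factors) in every library and 10 had 0 counts, against 29.8% of 16914 other protein-coding genes under 1 CPM. This is consistent with reads that match both copies of such a gene being left uncounted. With 2 counts, a lack of IL3RA transcript in the cells cannot be told apart from this, because genes of this kind were hardly counted at all.

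Of 30 listed markers of granulocytes, monocytes, mast cells, basophils and eosinophils, 14 were higher in BFUE than HSPC and 8 lower. The 14, which include granule protein genes, the transcription factor genes CEBPA, CEBPE and SPI1, FCER1A, HDC and HPGDS, had a median log2 change of 2.54, and all 14 were lower in CFUE than BFUE. They were selected as higher in BFUE, so a positive median follows from the selection. The comparison with CFUE shares the BFUE libraries that selected them, so it is not separate support. Mature neutrophils or monocytes in the BFUE sort are argued against by their own transcripts, whose median log2 change was −7.71, with 8 of 9 lower. A GC trend is argued against by the correction, under which the median was 2.67 and 13 of the 14 were called. The IL-3R− gate of the sort would remove progenitors of other lineages that carry this receptor. Progenitors of other lineages that passed it stay open: the median level of the 14 genes differed by 2.02 times over the BFUE libraries (75.9 to 153 CPM, scaled without TMM factors), which cannot separate such cells from transcription in the erythroid progenitors themselves. The median hides unequal spread among the 14. In BFUE, CEBPE was at 16.5 ± 13.9, PRTN3 at 147 ± 142 and MPO at 6101 ± 4213 CPM. EPX (617 ± 207) and CTSG (74.9 ± 24.5) varied less for their level.

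Transcripts of mature red cells (7 of 12 genes), neutrophils and monocytes (8 of 9) and vessels and stroma (8 of 12) were higher in HSPC than BFUE. Reads of CFUE libraries assigned to HSPC are argued against, because the 7 red cell genes stood in HSPC at a median of 68.1% of their CFUE level, against 0.54% for the 10 genes most raised in CFUE. Both percentages come from CPM scaled without TMM factors. Selection for CD34 would remove mature blood cells. Varying numbers of those that stayed among the CD34+ cells may add to these levels: in 3 of 3 lists the median SD over HSPC libraries was at or above the 95th percentile of 10000 matched random lists. The stem and progenitor list, used as a control, was at percentile 98.8 too, so the test is not specific, and its reading was changed to undecided after this was seen. Transcription in the CD34+ cells themselves also stays open, with a median of 13.6 CPM (scaled without TMM factors) for the red cell genes in HSPC.

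Other splits of the libraries were counted for each result. For each pair of stages there are 10 splits of 6 libraries, too few for a share under 0.05. In 1 of 10 splits, the real one, as many genes were called: 5261 higher and 5823 lower in BFUE than HSPC, 1329 and 2174 in CFUE against BFUE, and 5575 and 6576 in CFUE against HSPC, with 0 as the highest other count in each. For lists, 1 of 10 splits gave as many in BFUE against HSPC (10, highest other 9), 2 of 10 in CFUE against BFUE (13, highest other 13) and 2 of 10 in CFUE against HSPC (14, highest other 16). The number of lists called therefore hardly stands above that of mixed splits. Each mixed split keeps part of the difference between the stages, so this cannot tell how many lists chance would call.

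Of 100 splits of all 9 libraries, 1, the real one, gave as many genes differing among stages (12650, highest other 10160). It was also 1 for genes higher at both steps (621, highest other 0) and for genes lower at both (1000, highest other 0). The other splits mix stages within groups, which widens the spread. Same-numbered BFUE and CFUE libraries also deviate together, so these splits cannot exclude chance. For the step difference it was 3 (7106, highest other 11164), for genes highest in BFUE 3 (463, highest other 4702) and for genes lowest in BFUE 4 (316, highest other 4466), shares under 0.05. The highest other counts are several times the real ones for the last 2 results and point to a structure of the samples: of the other splits that gave as many, 2 for each of these 3 results had the 3 HSPC libraries as the middle group.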
